A study of Mus musculus with 6 samples.

How the data were processed

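RNA from skin tumours of male mice was measured on 6 one-colour Agilent arrays: 3 tumours labelled P2ry6+/+ (wild-type) and 3 labelled P2ry6-/- (knockout). Per the labels' protocols, 12 mice of each genotype received 195 nmol of the mutagen DMBA on shaved back skin in 200 uL of acetone, followed by 16 nmol of the tumour promoter TPA 2 times a week until week 22, and 0.2 ug of RNA per sample was labelled with Cy3. The labels number the tumours within each genotype but do not say that each came from a separate mouse, so p-values measure the spread between these samples only.

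Spot brightness was deposited by the authors as intensity on a linear scale, per the file headers: the processed signal is background-subtracted and spatially detrended, with surrogate values for dim spots, and the mean and local background signals are raw brightness. The extraction program was Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The series value table deposited by the authors holds log2 values. Set against each array's own processed signal, its columns gave r between 0.99945 and 0.99997 over 56605 probes, and every column had a median of 4.969, which is what quantile normalization without centring of genes produces; the tool behind it is not given in the sources used here. The files give probe coordinates on mouse build mm9.

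The values used were log2 of the processed signal minus each array's 75th percentile over non-control probes, so a value of 0 lies at that percentile. Each array held 62976 spots, of which 59305 were not controls. Spots with an outlier flag (68 to 184 per array) were left out and spots of a probe were averaged; 0 spots were saturated. A probe was tested if it was well above background on every array of at least 1 genotype, which 29720 of 56605 probes were. Names came from the RefSeq table of assembly GRCm38.p6, used for names only: 32994 probes matched by accession, 10224 by symbol and 520 through a synonym, and the other 12867 kept the array's name. Different probes of a gene were reduced to the one with the highest mean over all 6 arrays, which left 19751 features, 15922 of them with a gene name. Where another probe of a named gene that passed the filter went the other way, or differed by under 2-fold where the probe taken differed by more, the text says so.

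Genotypes were compared with a linear model and moderated statistics (limma 3.58.1, lmFit and eBayes, in R 4.3.3; tables were read with the data.table package, version 1.17.8), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are labelled knockout minus labelled wild-type. A second count took genes with an unadjusted p under 0.05 and at least a 2-fold difference. With 3 samples against 3, an exact permutation test cannot give a p below 0.1. A probe not well above background on any array of a genotype has only a bound there, and the fold is then given as "at least". The brighter genotype's mean is set against the dim genotype's mean. Per array, the latter takes the higher of the lowest signal among probes well above background and the probe's own. The SE and p of such a probe still use its dim values, which do not fully measure the spread between tumours.

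Before the data were examined, 33 gene lists were fixed for pathways, keratinocyte states and the cell types that a skin tumour sample can hold. Lists with at least 5 measured members (32 of them) were tested against all other genes with camera (preset correlation 0.01) and adjusted over the lists; camera with an estimated correlation and fry were alternatives. The genes named were fixed by a rule: P2ry6; the 15 named genes with the largest difference past the threshold and no overlap between genotypes in each direction; where fewer passed, those with the smallest p up to 10, given as not passing; and up to 4 members with the smallest p of each list described. Any other gene is said to have been chosen after its values were seen. The result of 1 gene that this rule selects is not reported here.

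The arrays had 54.2% to 59.4% of non-control spots well above background, and the number of arrays limits the precision. All 6 arrays lay on 1 slide and were scanned at 1 time, so slide and scan could not be set as blocks. The column of the slide was tried instead, after the data were examined. Labelled wild-type replicates 1, 2 and 3 lay in slide rows 1, 1 and 2, and labelled knockout replicates 1, 2 and 3 in rows 2, 3 and 3. Row nearly follows genotype, so an effect of row cannot be separated from genotype, and row was not tried. The other alternatives, planned before, were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, probes above background on all 6 arrays, the mean over a gene's probes, eBayes with trend and robust settings, array weights, the series value table, the replicate number as a block, and each sample left out in turn.

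The gene fit was tested on simulated data: 100 runs (raised from 20 after those were seen, as the share of unshifted lists called varied between draws) on 19751 genes with the real means and spreads, each with 200 genes changed. For the comparison of the genotypes it recovered 30.72% of genes changed 2-fold, 74.96% of those changed 4-fold, 94.08% of those changed 16-fold and 98.14% of those changed 64-fold, with a median of 8 false calls among 163 calls. The simulated values had no detection floor and the same spread in both genotypes, and the changed genes were drawn at random. These shares therefore do not carry over to genes at the floor or with a wide spread between tumours. The list test found a 20-gene list shifted by 1 on the log2 scale in 100% of runs and called an unshifted list in 1% of runs at an unadjusted p under 0.05; the simulated genes were independent of each other, which real genes of a list are not.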

Results

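Gene expression was measured in 6 skin tumours induced by DMBA and TPA on the backs of mice, 3 labelled wild-type for P2ry6 and 3 labelled knockout. P2ry6 encodes a G-protein-coupled receptor for uridine diphosphate. The comparison asks which genes differ between tumours labelled as having and as lacking this receptor's gene. Between 54.2% and 59.4% of the non-control spots of each array were well above background. The 75th percentile of the signal was 322 to 368 units on the labelled wild-type arrays and 277.1 to 299.6 units on the labelled knockout arrays. Slide row nearly follows genotype, so this gap cannot be assigned to either. Arrays of the labelled knockout tumours correlated with each other across genes at r = 0.982 to 0.984, and those of the labelled wild-type tumours at r = 0.962 to 0.980; genes are not independent replicates.

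P2ry6 itself was not lower in the tumours labelled knockout. Its brighter probe, on chromosome 7 from 108086152 to 108086211 (mm9), had a mean log2 signal of 0.57 ± 0.13 (SD, n = 3) in the labelled knockout tumours and 0.17 ± 0.33 (SD, n = 3) in the labelled wild-type tumours, a difference of 0.41 (SE 0.20, limma adjusted p = 0.450). The other probe, from 108112251 to 108112310, gave -0.70 ± 0.25 (SD, n = 3) against -1.24 ± 0.37 (SD, n = 3). Two-sided exact permutation tests gave p = 0.1 and p = 0.2 for these probes, where 0.1 is the smallest p the design allows. Both probes were well above background on all 6 arrays. The labels do not say which part of the gene was removed, and a probe outside that part does not check the genotype, so every direction below follows the labels. Of the 18 measured genes of the fixed list of P2ry6's neighbours on chromosome 7, 8 were higher and 10 lower in the labelled knockout tumours, with a median log2 difference of -0.02 (camera adjusted p = 0.413), and 0 passed the threshold over all genes tested or adjusted over the list alone. With no filter on dim probes the list passed (camera adjusted p = 0.032) at the same median. In that setting the median of all features was 0.187, against 0.017 in the main fit. The list then lay lower against the other genes without having moved itself.

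Genes of skeletal muscle and fat were among those lower in the labelled knockout tumours. The myosin heavy chain genes Myh8 and Myh4 were at least 166-fold and at least 82.1-fold lower (limma adjusted p = 0.038 and adjusted p = 0.011), and neither of the probes taken was well above background on any labelled knockout array. Adipoq, which encodes the fat-cell hormone adiponectin, was at least 4.66-fold lower (adjusted p = 0.0074). Cfd, which encodes adipsin, was at least 53.3-fold lower (adjusted p = 0.0092), and Car3, a carbonic anhydrase abundant in fat and muscle, at least 39.6-fold lower (adjusted p = 0.021). Another probe of Myh4 was well above background in both genotypes and differed by 0.23 on the log2 scale in the other direction.

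The smallest p of all belonged to Skint3, of a family of immunoglobulin-like genes expressed in skin and thymus on chromosome 4. Its brighter probe (chromosome 4 from 111973014 to 111973073, mm9) read 3.09 ± 0.67 (SD, n = 3) in the labelled wild-type tumours and was not well above background in any labelled knockout tumour, at least 125-fold lower (limma adjusted p = 0.00072), while a second probe of Skint3 differed by 0.20 in the other direction. Skint4 was at least 4.35-fold lower (adjusted p = 0.0032) and Skint11 at least 2.62-fold lower (adjusted p = 0.0031). D4Ertd617e, also on chromosome 4, was at least 4.19-fold lower (adjusted p = 0.0068). Other genes that were lower included the matrix genes Mfap5 (at least 9.68-fold, adjusted p = 0.020) and Col8a2 (at least 1.51-fold, adjusted p = 0.026), the adhesion receptor Adgrg6 (at least 7.99-fold, adjusted p = 0.0074) and the lectin gene Cd209f (at least 5.94-fold, adjusted p = 0.018). Plac9a fell by 2.95 on the log2 scale (SE 0.34, adjusted p = 0.047). Tmsb15b1 fell by 2.59 (SE 0.22, adjusted p = 0.013), with 2 of the 3 labelled knockout arrays well above background.

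Higher in the labelled knockout tumours were the zinc-finger genes Zfp979, Zfp949 and Zkscan7. Zfp979 was higher by 4.35 on the log2 scale (SE 0.44, limma adjusted p = 0.026; 2 of 3 labelled wild-type arrays were well above background), Zfp949 by 2.70 (SE 0.23, adjusted p = 0.015) and Zkscan7 by 1.81 (SE 0.20, adjusted p = 0.038). Other probes of Zkscan7, well above background on all 6 arrays, differed by 0.29 and 1.19. Ibsp, which encodes bone sialoprotein, was at least 3.69-fold higher (adjusted p = 0.012), and Afm, which encodes the vitamin E-binding protein afamin, at least 5.68-fold higher (adjusted p = 0.037). Gm5105 was at least 3.09-fold higher (adjusted p = 0.033), and Gm10413 was higher by 1.71 (SE 0.16, adjusted p = 0.018). The next 3 named genes by p did not pass: the adenosine kinase gene Adk with a difference of 1.06 (adjusted p = 0.071; -0.22 at another of its probes), Trim43b with 1.43 (adjusted p = 0.071) and the complement-activating protease gene Masp2, at least 2.71-fold higher (adjusted p = 0.080).

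**Figure D1:**
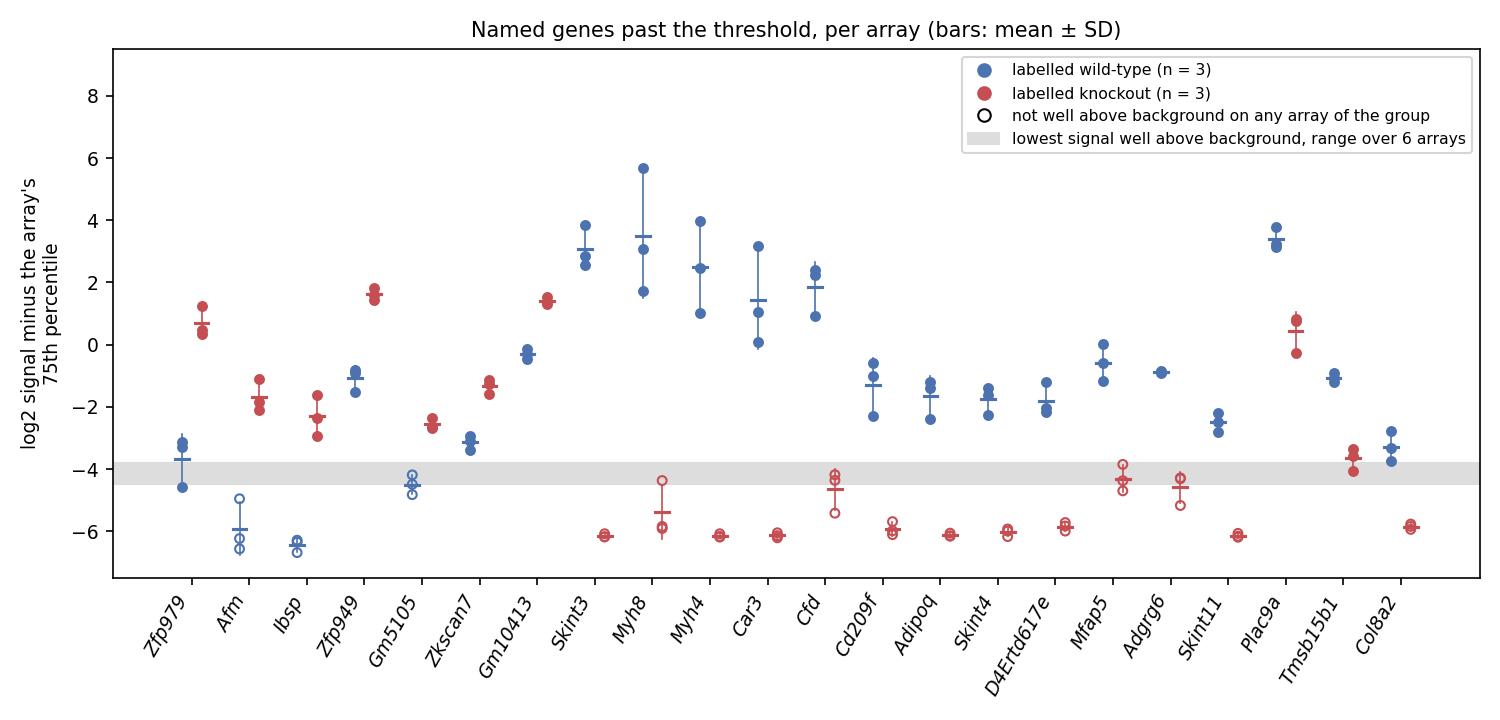
Log2 signal minus the array's 75th percentile (vertical axis) for the named genes past the threshold, 1 point per array, with the mean and SD of each genotype (n = 3). Open points lie in a genotype in which no array was well above background; the labelled knockout values of Skint3, Myh4, Car3 and Adipoq sit near -6.1, below the grey band of the lowest signals that were.

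In all, 32 of 19751 features passed limma's adjusted threshold, 10 higher and 22 lower in the labelled knockout tumours, and 27 of them carry a gene name. Most of the 32 were not well above background on any array of 1 genotype. Their dim values can vary little, as for Skint3 and Adipoq (labelled knockout SD 0.057 and 0.053). The adjusted p of such features therefore rests partly on the spread of the floor. A further count, at an unadjusted p under 0.05 and at least 2-fold, held 875 features, 404 higher and 471 lower. The genotypes did not overlap for 3850 features, or 19.5%. The 10% that chance gives is an average over splits of the arrays, and genes that vary together can put any split above it. The filter also kept probes by genotype, which favours features that separate the genotypes, so 10% is not a full reference here. The adjusted count moved with the tumours used: it was 38, 125 and 62 without labelled wild-type replicates 1, 2 and 3, which shared 23, 31 and 26 of the 32. It was 16, 16 and 13 without knockout replicates 1, 2 and 3, which shared 11, 12 and 10. It was 10 after normexp background correction, 18 with no filter on dim probes, 5 with probes above background on all 6 arrays, 89 with array weights and 21 with the slide column as a block. Among the named genes past the threshold, Plac9a and Zkscan7 kept their calls least often, in 4 of 17 and 5 of 17 alternatives.

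Among the fixed lists, the muscle list shifted furthest. All 17 measured skeletal muscle genes were lower in the labelled knockout tumours, with a median log2 difference of -4.47 (-3.80 with genes below background at their bound; camera adjusted p = 1.78e-16; adjusted p = 0.565 with an estimated correlation), and 16 were lower when adjusted over the list alone against 1 over all genes tested. Tnnc2 and Myl1, of the contractile fibre, were at least 175-fold and at least 79.3-fold lower and did not pass over all genes (limma adjusted p = 0.080 and adjusted p = 0.088); Tnnt3 differed by -5.79 (adjusted p = 0.170). Another probe of Myl1, well above background on all 6 arrays, differed by -0.11, and it differed by 0.34, in the other direction, without wild-type replicate 2. The mean level of the list was 3.64 in labelled wild-type replicate 2, 0.59 in replicate 3 and -0.78 in replicate 1, against -3.44 to -3.70 in the labelled knockout tumours.

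Fat-cell genes were lower in the labelled knockout tumours as well. Among the labelled wild-type tumours the mean level of their list was 1.09, 1.83 and 0.68 in replicates 1, 2 and 3. Muscle there ran in another order, with replicate 1 lowest. Of 12 measured adipocyte genes, 10 were lower, with a median log2 difference of -3.34 (-2.33 at the bounds; camera adjusted p = 4.76e-09; adjusted p = 0.415 with an estimated correlation). Adjusted over the list alone, 8 were lower, against 3 over all genes (Adipoq, Cfd and Car3). Pparg, the master regulator of fat-cell formation, differed by -3.62 (SE 0.53, limma adjusted p = 0.092).

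Skin appendage genes also fell as groups under the preset correlation. Of 14 sebaceous gland genes 13 were lower, with a median of -2.44 (-2.33 at the bounds; camera adjusted p = 2.21e-06; adjusted p = 0.565 with an estimated correlation); Scd1, which desaturates fatty acids, differed by -2.45 (limma adjusted p = 0.316) and Awat2, a wax synthase gene, by -2.99 (adjusted p = 0.305). Of 24 hair follicle genes 22 were lower, with a median of -2.39 (camera adjusted p = 3.03e-06; adjusted p = 0.697 with an estimated correlation). The inner root sheath keratin genes Krt71 and Krt25 differed by -6.56 (SE 1.64, limma adjusted p = 0.228) and -5.96 (SE 1.57, adjusted p = 0.236), with 2 of 3 and 1 of 3 labelled knockout arrays well above background. In both lists 0 members passed over all genes or adjusted over the list alone. Levels varied widely between tumours: the hair list averaged 2.75, 1.59 and -1.04 in labelled wild-type replicates 2, 1 and 3, and -0.48, -2.14 and -2.27 in labelled knockout replicates 2, 3 and 1. Without wild-type replicate 2 the medians of the muscle, fat, hair and sebaceous lists were -2.82, -2.30, -1.39 and -1.32. That of muscle was -5.42 without replicate 1, and that of hair -4.07 without replicate 3. With only probes above background on all 6 arrays the medians of the muscle, fat and hair lists were -2.48, -0.55 and -0.27, and the hair list did not pass (camera adjusted p = 0.084). With normexp those of muscle and fat were -2.76 and -1.31.

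Interferon-response genes were higher in the labelled knockout tumours. Of 20 measured members 19 were higher, with a median log2 difference of 0.85 (camera adjusted p = 3.61e-08, and adjusted p = 0.565 with an estimated correlation). The mean level of the list was 0.59, -0.30 and 0.16 in labelled knockout replicates 1, 2 and 3. It was -0.76, -0.39 and -0.71 in labelled wild-type replicates 1, 2 and 3. The median was 0.59 without knockout replicate 1 and 0.58 with normexp, and the list passed in both. Adjusted over the list alone 5 were higher, against 0 over all genes. Among them were the RNA sensor gene Ifih1, higher by 0.95 (SE 0.16, limma adjusted p = 0.141 over all genes), Oas1a by 1.11 (SE 0.20, adjusted p = 0.146), Mx2 by 1.37 (SE 0.24, adjusted p = 0.146; 1 of 3 labelled wild-type arrays well above background) and Irf9 by 0.89 (adjusted p = 0.206; named after its values were seen).

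Genes of the outer epidermis were higher as well. Of 31 genes of epidermal differentiation and the cornified envelope 26 were higher, with a median of 0.53 (camera adjusted p = 7.76e-06; adjusted p = 0.565 with an estimated correlation), and 8 were higher adjusted over the list alone against 0 over all genes. The median was 0.33 with array weights. Examples are repetin (Rptn), higher by 1.29 (SE 0.28, limma adjusted p = 0.201), hornerin (Hrnr) by 1.38 (SE 0.35, adjusted p = 0.229) and the late cornified envelope gene Lce1d by 0.94 (SE 0.21, adjusted p = 0.201). Of 22 hyperproliferation and alarm genes of keratinocytes 16 were higher, with a median of 0.32 (camera adjusted p = 0.0092; adjusted p = 0.565 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. This call ended with normexp (median 0.20, adjusted p = 0.069), quantile normalization (median 0.19, adjusted p = 0.0905), the series value table (adjusted p = 0.083) and no filter on dim probes (adjusted p = 0.136). It also ended without wild-type replicate 3 (adjusted p = 0.064), and the median was 0.54 without wild-type replicate 1. The values for S100a9 and Stfa2 were 0.63 (limma adjusted p = 0.267) and 1.75 (adjusted p = 0.236). The basal keratinocyte list did not pass: 9 of 13 were higher, with a median of 0.14 (camera adjusted p = 0.413). The muscle, fat and appendage lists, which moved the other way in the same samples, are given above.

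Cell cycle genes were lower by a small amount in 25 of 26 cases, with a median log2 difference of -0.28 (camera adjusted p = 0.00018; adjusted p = 0.781 with an estimated correlation). Tyms differed by -0.56 (SE 0.23, limma adjusted p = 0.368) and Mcm5 by -0.43 (SE 0.20, adjusted p = 0.423); 0 members passed. Labelled knockout replicate 1 had the highest level of this list on any array (2.77), and the call ended without knockout replicate 2 (median -0.17, adjusted p = 0.055), while the median was -0.52 without knockout replicate 1. Genes that the ERK pathway induces as its own feedback were lower in 11 of 16 cases, with a median of -0.45 (camera adjusted p = 0.016; adjusted p = 0.565 with an estimated correlation). The ERK phosphatase gene Dusp4 was the 1 member that passed adjusted over the list alone, with -2.49 (SE 0.45, limma adjusted p = 0.146 over all genes). This call ended without wild-type replicate 3 (median -0.23, adjusted p = 0.077) and without knockout replicate 1 (adjusted p = 0.076). It also ended with array weights and with the slide column as a block (adjusted p = 0.084 in both), and its median was -0.28 with the mean over a gene's probes. Oxidative phosphorylation genes were lower in 15 of 18 cases by a median of -0.16 (camera adjusted p = 0.049; adjusted p = 0.781 with an estimated correlation); the values for Ndufb5 and Atp5b were -0.25 and -0.28 (adjusted p = 0.496 and adjusted p = 0.536). That call ended without wild-type replicate 1 (adjusted p = 0.168) or 3 (adjusted p = 0.077) and without knockout replicate 2 (adjusted p = 0.190) or 3 (adjusted p = 0.187). It also ended with the mean over a gene's probes (median -0.08, adjusted p = 0.121). Its median lay between -0.08 without knockout replicate 2 and -0.26 without knockout replicate 1, and the muscle list was lower in the same tumours (median -4.47). Within the labelled wild-type tumours, however, the oxidative phosphorylation list averaged 5.723, 5.638 and 5.535 in replicates 1, 3 and 2. The muscle list ran in the reverse order there, at -0.78, 0.59 and 3.64.

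**Figure D2:**
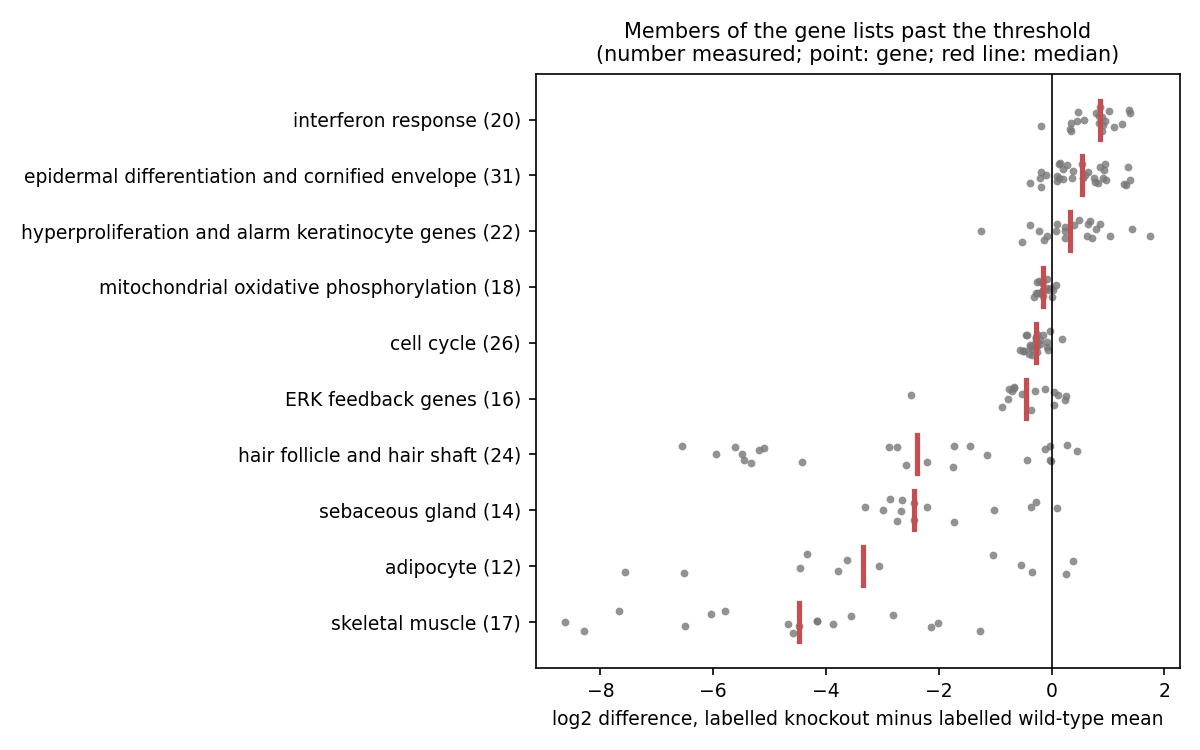
Log2 difference between the labelled knockout and labelled wild-type means (horizontal axis) for each measured member (grey points) of the 10 lists past the threshold under the preset correlation, with each list's median in red. Muscle, fat, sebaceous and hair genes spread down to below -3 while the interferon and cornification lists lie mostly above 0.

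Of the 32 tested lists, 10 passed with the preset correlation, 3 higher and 7 lower, 0 passed with an estimated correlation, and fry, which asks only whether a list's own genes move one way, called 1 (the adipocyte list, adjusted p = 0.030). Other divisions of the same 6 arrays into 3 and 3 gave up to 16 lists at the preset correlation, so the count of lists does not set the genotypes apart from other groupings.

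The other lists of signalling genes did not pass. The median was -0.04 for 22 YAP/TAZ targets (camera adjusted p = 0.575), where Ccn2 differed by -1.31 (limma adjusted p = 0.231), 0.15 for 15 Wnt/beta-catenin targets (adjusted p = 0.812), -0.06 for 20 immediate early genes (adjusted p = 0.305) and 0.42 for 15 nucleotide receptors and ectonucleotidases (adjusted p = 0.057; adjusted p = 0.043 with median centring, 0.0495 with array weights, 0.040 without wild-type replicate 2 and 0.020 without knockout replicate 1). Without wild-type replicate 3 the nucleotide receptor list had a median of 0.24 (camera adjusted p = 0.207). Inflammatory cytokines and chemokines had a median of 0.74 over 22 genes (camera adjusted p = 0.058), with 1.90 for Cxcl10 (limma adjusted p = 0.277) and 1.65 for Ccl8 (adjusted p = 0.309). This list passed without knockout replicate 1 (median 1.03, camera adjusted p = 0.0024) and without wild-type replicate 2 (1.02, adjusted p = 0.0091). It also passed with median centring, eBayes with trend, array weights and the slide column (adjusted p = 0.022, 0.047, 0.0090 and 0.045). Its median was 0.25 without wild-type replicate 3 and also 0.25 without knockout replicate 3. Among immune and stromal cell types, the medians were 0.41 for neutrophil genes (camera adjusted p = 0.096), 0.05 for macrophage genes (adjusted p = 0.305), 0.26 for T and NK cell genes (adjusted p = 0.215), -0.49 for B and plasma cell genes (adjusted p = 0.215), 0.14 for mast cell genes (adjusted p = 0.575), 0.28 for dendritic and Langerhans cell genes (adjusted p = 0.196), 0.41 for fibroblast and collagen genes (adjusted p = 0.239), -0.19 for endothelial genes (adjusted p = 0.156) and -0.70 for melanocyte genes (adjusted p = 0.168). Of the macrophage genes Arg1 was higher when adjusted over the list alone, by 1.06 (SE 0.20, limma adjusted p = 0.158 over all genes). The medians were -0.01 for EMT and invasion genes (camera adjusted p = 0.774), 0.21 for hypoxia and glycolysis genes (adjusted p = 0.183), -0.19 for heat shock genes (adjusted p = 0.168), -0.29 for NRF2 and xenobiotic genes (adjusted p = 0.199), 0.10 for p53 targets (adjusted p = 0.952) and 0.18 for circadian clock genes (adjusted p = 0.313). Of the clock genes Bhlhe41 was lower adjusted over the list alone, at least 1.17-fold (limma adjusted p = 0.179 over all genes). In these lists 0 members passed over all genes, and apart from Arg1 and Bhlhe41 0 passed adjusted over the list alone. Of all 22 tested lists that did not pass, 13 passed without 1 or another tumour. Over the tumours left out, the fibroblast median ran from 0.02 to 0.66, the neutrophil median from 0.16 to 0.75, the endothelial median from -0.33 to -0.01 and the macrophage median from -0.13 to 0.26. The mast cell median ran from -0.26 to 0.36 and the dendritic median from 0.09 to 0.45. The T and NK cell median ran from 0.11 to 0.49 and that of B and plasma cell genes from -0.73 to -0.23. The smallest p was that of the melanocyte list without knockout replicate 2 (median -1.67, camera adjusted p = 3.99e-05). With no filter on dim probes the YAP/TAZ, immediate early, endothelial, melanocyte, heat shock and NRF2 lists passed (adjusted p = 0.031, 0.019, 0.0029, 0.0093, 0.013 and 0.0048). The median of all features was 0.187 in that setting, so a list can pass there as lower with its own median unmoved. With the slide column the endothelial and melanocyte lists passed (adjusted p = 0.00087 and 0.0039). With normexp the heat shock list passed (adjusted p = 0.044), and with array weights the neutrophil list (adjusted p = 0.021). The median and mean differed in sign for the Wnt (mean -0.23), EMT (0.08) and p53 (-0.02) lists; camera's direction went with the mean for Wnt and with the median for the other 2. The papilloma progression list had 4 measured keratin genes, too few for the main test, and passed with no filter on dim probes (median -1.65, camera adjusted p = 0.0048). It did not pass without wild-type replicate 1 (adjusted p = 0.237) or 3 (adjusted p = 0.081), where it was also tested. Its mean level was 2.33 in labelled knockout replicate 3, the highest of any array, and -3.59 in replicate 2. Krt18 differed by -2.32 (SE 1.55, limma adjusted p = 0.571) and Krt13 by -1.60 (SE 2.34, adjusted p = 0.813). The value for Krt13 turned to 0.90 without knockout replicate 2 and to 0.002 with the slide column.

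**Figure D3:**
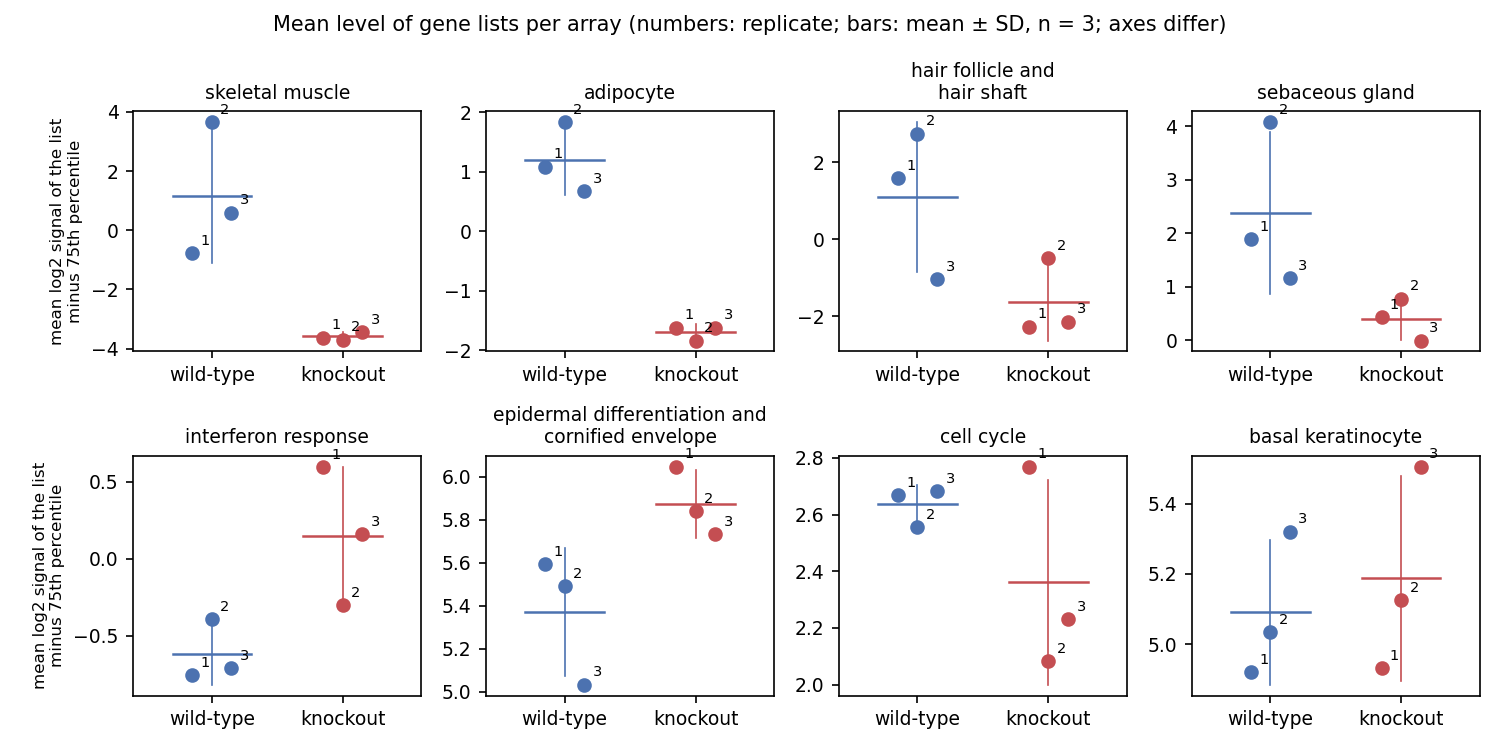
Mean log2 signal of 8 gene lists on each array, relative to the array's 75th percentile (vertical axes, which differ), with the replicate number beside each point and the mean and SD of each genotype (n = 3). Muscle and fat levels separate the genotypes, labelled wild-type replicate 2 has the highest muscle (3.64) and sebaceous (4.07) levels, and the basal keratinocyte levels of the genotypes overlap.

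The median SD over genes was 0.275 among labelled wild-type tumours and 0.204 among labelled knockout tumours, a ratio of 1.345. It was 1.274, 0.926 and 1.103 without wild-type replicates 1, 2 and 3, and 1.985, 1.588 and 1.485 without knockout replicates 1, 2 and 3. A median SD over fewer samples is lower by construction, so these ratios are not on the scale of the first.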

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

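The slide column as a block was chosen after the data were examined. Slide and scan as blocks were not run, since all 6 arrays share 1 of each. Slide row, which nearly follows genotype, was not run either. The 10 lists kept their direction under all 19 alternatives. P2ry6 stayed higher in the labelled knockout tumours, by 0.22 to 0.51, and did not pass in any fit. Scalings moved the median of all genes by under 0.1. With no filter on dim probes it was 0.187 over 37003 features, which places lists lower against the other genes. The cause was not tested for any change below except where the samples or genes tested were fewer. Signal over background limits the folds of genes at the floor, which normexp with its offset compresses.

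The 32 genes changed (10 higher, 22 lower) became 10 with normexp (5 and 5), 18 with no filter (5 and 13; 1317 and not 875 genes at an unadjusted p under 0.05 and 2-fold), 5 with probes above background on all 6 arrays, a filter that removes genes at the floor in 1 genotype (3 and 2), 89 with array weights (44 and 45), 21 with the slide column (5 and 16) and 68 at an adjusted p under 0.10. The 2-fold count was 390 with normexp and 558 with probes above background on all arrays. Of the 22 named genes past the threshold, 6 passed with normexp, 12 with no filter, 2 with probes above background on all arrays and 13 with the slide column. In that stricter filter another probe stood for Skint3 (0.20) and for Myh4 (0.23), which reversed their directions. Leaving out single samples gave 13 to 125 genes (3 to 65 higher, 10 to 60 lower), 818 to 1240 genes at 2-fold, 7 to 21 of the named genes, 9 to 17 lists and a spread ratio of 0.926 to 1.985.

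Whether the numbers of the tumours pair them stays open, as the labels do not say. Same-numbered tumours correlated in their deviations from the genotype means at 0.06, 0.26 and 0.14. Differently numbered tumours correlated at -0.20 to 0.10, and wild-type replicate 1 correlated best with knockout replicate 3 (0.10). With the replicate block, 5 genes passed (1 higher, 4 lower; 3 of the named genes), and 13 lists, among them nucleotide receptor, fibroblast and melanocyte (adjusted p = 0.015, 0.013 and 0.013), which had not passed.

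The list count of 10 became 17 with no filter, 0 with an estimated correlation and 1 with fry. Adjusted p with an estimated correlation and with fry was 0.565 and 0.419 for ERK feedback, 0.565 and 0.2135 for interferon, 0.7805 and 0.561 for cell cycle, 0.565 and 0.305 for epidermal differentiation, 0.565 and 0.254 for the alarm genes, 0.697 and 0.549 for hair follicle, 0.565 and 0.396 for sebaceous gland, 0.565 and 0.2135 for muscle and 0.7805 and 0.561 for oxidative phosphorylation; for adipocyte it was 0.415 with an estimated correlation and 0.030 with fry. ERK feedback was at 0.084 with array weights and 0.084 with the slide column. The alarm genes were at 0.069 with normexp, 0.0905 with quantile normalization, 0.083 with the series value table and 0.136 with no filter. Hair follicle was at 0.084 with probes above background on all arrays (median -0.27 and not -2.39), and oxidative phosphorylation at 0.121 with the mean over probes. Without single samples, adjusted p ran from 0.000996 to 0.077 for ERK feedback, 7.38e-11 to 0.055 for cell cycle, 0.00232 to 0.0636 for the alarm genes and 0.00137 to 0.190 for oxidative phosphorylation, and the EMT list, which had not passed, reached 0.048 in the other direction without wild-type replicate 2 (0.048 to 0.950 over the samples left out). Of the 22 lists that had not passed, 13 did without at least 1 sample; besides EMT, the smallest adjusted p was 3.99e-05 for melanocyte, 0.0024 for inflammatory, 0.0047 for fibroblast, 0.0058 for neutrophil, 0.00835 for endothelial, 0.018 for macrophage, 0.019 for B and plasma cell, 0.020 for nucleotide receptor, 0.020 for NRF2, 0.027 for immediate early, 0.030 for dendritic and 0.030 for T and NK cell genes.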

Other observations

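The counts of splits and the tests of second lists and of other probes were planned before their results were seen; those of scaling, neighbouring genes, chromosome 7 and basal keratinocytes were chosen after.

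A few genes of type 2 immunity had large differences that missed the threshold; they were chosen after their values were seen. Chil4 and Chil3, chitinase-like genes of alternatively activated macrophages, were higher in the labelled knockout tumours by 5.61 (SE 1.07, limma adjusted p = 0.164) and 4.68 (SE 0.81, adjusted p = 0.141). The cytokine gene Il4 differed by 3.51 (SE 0.69, adjusted p = 0.175; 2 of 3 labelled wild-type arrays well above background) and Ccl11, which encodes the eosinophil chemokine eotaxin, by 2.86 (SE 0.58, adjusted p = 0.181), each without overlap between the genotypes. A wider type 2 response may underlie these values. In 20 measured type 2 genes not looked at before, however, 12 were higher and 8 lower, with a median of 0.2421 (camera p = 0.304; 0.644 with an estimated correlation), which falls between the bounds set beforehand and leaves it open; Il4ra differed by 0.59 and the alternative-activation gene Retnla by -1.41, with 1 of 3 labelled knockout arrays well above background for Retnla.

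A few genes that passed lie outside the naming rule and were chosen after their values were seen. Crybg1 was 5.12-fold lower in the labelled knockout tumours (SE 0.15 on the log2 scale, limma adjusted p = 0.0049), the adhesion gene Alcam 3.51-fold lower (adjusted p = 0.033), the retinaldehyde dehydrogenase gene Aldh1a1 3.14-fold lower (adjusted p = 0.039) and the matrix gene Fbln7 5.49-fold lower (adjusted p = 0.012), all measured above background on all 6 arrays. Gspt2 was at least 1.25-fold lower (adjusted p = 0.021).

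With 3 tumours against 3 there are 10 splits, too few for a share under 0.05. For the genes changed, 1 of the 10 splits, the real one, gave as many: 32 against 3 at most in the others. For genes at an unadjusted p under 0.05 and 2-fold it was again 1 split, with 875 against 530 at most. The filter on dim probes kept probes by genotype, which favours the real split in both counts. The 3 and the 530 both came from the split that follows the slide's columns. For lists, 8 of the 10 splits gave as many as the real 10, with 16 at most; the split that follows the slide's columns gave 12 lists, and with the column as a block the genotypes gave 12.

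Muscle and fat genes were lower in the labelled knockout tumours. RNA of muscle and fat beneath the skin in the labelled wild-type samples is a candidate explanation. In a further list of 30 muscle genes, sharing no member with the fixed lists, all 20 measured were lower with a median of -2.096 (camera p = 9.11e-11, and p = 0.169 with an estimated correlation). Muscle genes of the same samples would be lower together under other causes too, so that list does not single out this one. A further fat list did not repeat the size of the fixed list's shift. In it 9 of 13 genes were lower and 4 higher, with a median of -0.24 (camera p = 0.0049, and p = 0.199 with an estimated correlation). Scaling between arrays does not account for the lower muscle genes, since the muscle list's median stayed at or below -2.762 under 4 other settings. It was -4.53 with quantile normalization, -4.51 with median centring and -4.525 with the series value table. The -2.762 came from normexp, which changes the background correction and keeps the scaling. The depth at which tumours were excised and a growth of tumours into muscle that differs by genotype both stay open, as the labels record neither.

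The probes taken for Skint3, Skint4 and Skint11 were not well above background in any labelled knockout tumour, while another probe of Skint3 was in all 3. Some other called features lie near each other in the genome. A different strain background in the 2 genotypes is a candidate explanation. Its rule asked for more pairs of genes within 2 Mb, among the 200 with the smallest p, than in any other split. That was not met: the real split had 83 pairs and another split 289, which by the rule counts against strain. Of the 289, 80.3% held a keratin or keratin-associated gene. Without such genes, a comparison added after that count was seen, the real split's 83 compared with 75 at most. The explanation was left open on that ground, a choice also made after the count was seen. A sequence variant under a single probe cannot be told apart either, as 70% of the other probes of called genes went the same way by at least 2-fold. Those were the other probes of Cfd, Adgrg6, Alcam, Zfp949 and Gm10413 and 1 of Zkscan7, while those of Skint3 and Myh4 and 1 of Zkscan7 did not. Most called features, Skint4 and Skint11 among them, had no other probe that passed the filter. A segment carried along beside P2ry6 alone is argued against, since 0 of 32 called features lie on chromosome 7. Regulation by the receptor was not tested.

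Interferon and cornification genes were higher in the labelled knockout tumours. An interferon response beyond the fixed list may be present: in a further list of 28 measured interferon genes 21 were higher, with a median of 0.4033 (camera p = 4.81e-05; p = 0.069 with an estimated correlation), among them Irf1, Parp9 and Dtx3l at 0.83, 0.72 and 0.79. Dilution of keratinocyte RNA by other tissue in the labelled wild-type samples cannot be told apart for the cornification genes, because their median exceeded that of basal keratinocyte genes by 0.394 (permutation of genes between the lists, p = 0.173). Infection, inflammation and genotype as sources of the interferon values stay open.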
